A study of Mus musculus with 8 samples.

How the data were processed

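The series holds RNA sequencing of whole testis from C57BL/6 mice aged 6 weeks, and of RNA recovered with an antibody against RNF17 from testis lysate, in animals heterozygous or homozygous for a disrupted Rnf17 gene. RNF17 is a germ cell protein with Tudor domains, which bind methylated arginines on PIWI proteins. There are 8 libraries in 4 groups of 2: heterozygous testis, homozygous testis, heterozygous RNF17 immunoprecipitate (IP) and homozygous RNF17 IP. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the antibody was used at 1 in 500 for 10 hours, beads were added for 2 hours and washed 5 times, cDNA was made from 1 µg of total RNA with primers chosen to avoid ribosomal RNA, and fragments of 350 to 500 bp were selected. No label says whether the 2 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

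The deposited tables hold whole-number counts of reads that the authors assigned to genes, to transposon families by uniquely mapped reads, and to transposon families by multiply mapped reads. Per the submitters' processing notes, STAR, DESeq and the mouse build mm9 were used; their versions, their roles and the counting rules are not given in the sources used here. The lysate columns of the IP tables were compared with the testis columns of the testis tables, and all 12 repeated columns were identical, so the testis libraries served as the input of the IPs. No column was left unmapped (0 columns). The gene table has 19276 entries: 19076 gene symbols and 200 entries named as piRNA precursor loci, 100 in sense and 100 in antisense. Of the symbols, 17332 are current in the reference annotation, 1598 are older symbols and 146 were not matched. The reference genome was another build than the tables use, so no coordinates are printed. Each transposon table has 1268 entries, for 634 families in sense and antisense orientation. How the authors assigned strand is not stated beyond these suffixes, and families or histone genes with near-identical copies are uncertain where reads could be split between them.

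The authors' deposited table of genes that differ between homozygous and heterozygous testes gives, per the file headers, a mean normalised signal per genotype, a log2 fold change whose size is below that of the ratio of the means in the same table, its standard error as a score, and p-values with adjusted p-values. It was used only for comparison.

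Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM scaling and the filterByExpr filter on low counts, and called at a Benjamini-Hochberg adjusted p under 0.05. Each comparison of 2 groups was fitted on its own 4 libraries. The comparisons were homozygous against heterozygous testis, heterozygous against homozygous IP, each IP against the testis libraries of its genotype, and the interaction, which is the log2 ratio of IP to input in heterozygotes minus that in homozygotes and was fitted on all 8 libraries. Transposon counts were scaled by the TMM effective library sizes of the gene table, so that a change of the whole transposon pool is kept. Values per library are CPM, read counts divided by these library sizes on the usual edgeR scale, and are computed within each comparison, so a gene's CPM in a library differs slightly between comparisons. Group values are means with the SD over n = 2 libraries, and log2 fold changes carry the standard error (SE) from the edgeR test. Where a group had 0 reads, a fold is a lower bound computed against a floor of 3 reads over the group; floors cover counting error only.

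Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, the correlation between genes preset to 0.01 and adjustment over the lists, each as a comparison of the list with all other genes. The lists were markers of spermatogonia, meiotic prophase, pachytene spermatocytes, round spermatids and elongating spermatids; of Sertoli, Leydig and peritubular myoid cells, macrophages, endothelium, blood and epididymis; and genes of the piRNA pathway, ribosomal proteins, the mitochondrial genome, replication-dependent histones, the interferon response, p53 targets, heat shock and transposon control. Transposon families were grouped by name into classes, of which 2, DNA transposons and satellites, held no family in the tables. The design, these lists and classes, the alternatives and the naming rule were chosen before the data were examined. By that rule, Rnf17 is always named. From each list, up to 3 members past the threshold with the smallest adjusted p are named, or the member with the highest mean where none passed. Also named are the 5 largest rises and 5 largest falls past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups, and the family with the most reads of each transposon class. In the testis, in the heterozygous IP against its input and in the interaction, edgeR called no gene, so the same rule was also applied to the calls of DESeq2, a step chosen after the data were examined. The list of piRNA precursor entries was also added then. Some genes that met the rule are not used here.

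The alternatives were the Wald test of DESeq2 1.42.0, DESeq2 size factors in the edgeR fit, no filter on low counts, the replicate number as a block, TMM within the transposon table, camera with an estimated correlation, the fry test, and leaving out each library in turn. Fry tests a list against no change, whereas camera compares the list with all other genes. A fit without 1 library leaves 1 group with a single library, which is then assumed to vary like the other groups. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

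The tests were tried on simulated counts drawn from the real means and library sizes, with 200 of the genes changed 2-fold, 4-fold or 8-fold. With the spread of the testis libraries, the edgeR test recovered 0%, 0% and 13.6% of the changed genes, and 5 of its 14 calls were unchanged genes. With the spread of the IP libraries it recovered 50.7%, 82.1% and 98.5%, and 15 of 169 calls were unchanged genes. For the interaction it recovered 0%, 0% and 1.5%. Among transposon entries, 100 of which were changed, it recovered 2.9%, 3% and 81.8% in the testis, 44.1%, 100% and 100% in the IP, and 0%, 3% and 15.2% in the interaction. Camera called none of 17 lists when none was moved (0 calls), and called the 1 list that was moved. For camera the counts were drawn independently per gene with a fixed spread, not the spread of the testis libraries. That trial therefore does not show how camera behaves with noisier libraries or correlated genes.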

Results

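Gene reads per library numbered 6140624 and 19838802 in heterozygous testis, 7260047 and 50575649 in homozygous testis, 9222913 and 5858753 in heterozygous IP, and 5661754 and 7344970 in homozygous IP, in the order of replicates 1 and 2. Between 15489 and 17723 entries were detected per library. Across 14180 genes, which are not independent replicates, the log2 CPM of the 2 libraries of a group correlated at r = 0.979 for the heterozygous IP, 0.961 for the homozygous IP, 0.927 for the homozygous testis and 0.877 for the heterozygous testis. The replicate 1 testis libraries of both genotypes carried more transposon reads per gene read than the replicate 2 libraries: 19.3 and 18.8 uniquely mapped transposon reads per 100 gene reads in replicate 1 of heterozygotes and homozygotes, against 6.3 and 8.01 in replicate 2.

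The targeted gene followed the labels. Rnf17 stood at 535 ± 35.6 CPM in heterozygous and 74.7 ± 34.1 CPM in homozygous testis (SD, n = 2), a log2 fold change of -2.84 (SE 0.61). It missed the threshold in edgeR (adjusted p = 0.139) and passed it in DESeq2 (adjusted p = 5.96e-04), and homozygous replicates held 0.0992 and 0.176 of the level of the heterozygous library of the same number. Without heterozygous replicate 1 or 2 it passed in edgeR, but such a fit leaves heterozygous testis a lone library and adds no support. In the authors' deposited table Rnf17 had mean normalised counts of 7751 and 1087 and a log2 fold change of -2.17, with an adjusted p of 0.00139. In the IPs, Rnf17 RNA was at 1246 ± 49.3 CPM in heterozygotes and 290.2 ± 118.8 CPM in homozygotes, a log2 difference of 2.10 (SE 0.27, edgeR adjusted p = 1.85e-04).

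The comparison of homozygous with heterozygous testes asked how the transcriptome differs when RNF17 is lost. Genes of elongating spermatids, the cells that condense their chromatin and build the sperm tail, were far lower as a group in homozygous testes: the median log2 fold change of the 37 measured genes was -4.28, and 36 of the 37 lay below 0. Genes of round spermatids, the haploid cells that precede them, were lower as a group too, with a median of -1.74 over 33 genes. Sertoli cell genes (median 0.81 over 27 genes), Leydig cell genes (0.61 over 19), spermatogonial genes (0.81 over 17), peritubular myoid genes (0.87 over 12) and macrophage genes (0.59 over 15) were higher as groups. Camera called these 7 of the 17 lists it could test, and none of the 7 calls held with a correlation estimated per list (adjusted p = 0.515 with an estimated correlation for each). In whole testis, such differences cannot tell a change in the mix of cells from a change of expression within cells.

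Prm1, which encodes a protamine that replaces histones in sperm chromatin, had 1025 ± 1015 CPM in heterozygous and 5.48 ± 2.80 CPM in homozygous testis. Its log2 fold change was -7.56 (SE 1.17, edgeR adjusted p = 0.133, DESeq2 adjusted p = 3.57e-16). Prm2 was at 1261 ± 1182 against 7.32 ± 6.71 CPM. Tnp1 and Tnp2, the transition proteins that precede the protamines, were at 4552 ± 4760 against 29.7 ± 16.5 CPM and at 267 ± 236 against 4.53 ± 1.99 CPM. Odf1, a component of the outer dense fibres of the sperm tail, was at 2432 ± 2306 against 55.7 ± 13.7 CPM. Prm2, Tnp2 and Odf1 were singled out after their values were seen, and Prm1 and Tnp1 by the rule applied to DESeq2 calls. With 1 of the 4 libraries left out, the log2 fold change of Prm1 lay between -8.35 without heterozygous replicate 1 and -5.84 without heterozygous replicate 2. The large SDs reflect the heterozygous libraries: homozygous Prm1 was 0.0243 of the heterozygous level in replicate 1 and 0.00201 in replicate 2. The list median was -2.51 between the replicate 1 libraries and -4.89 between the replicate 2 libraries. Adjusted over the list alone, edgeR counted 32 of the 37 elongating spermatid genes as lower and none as higher, and DESeq2 over all genes counted 30; over all genes edgeR counted 0. The predefined member with the highest mean, Odf2, had 7822 ± 5194 against 2284 ± 631 CPM (log2 fold change -1.78, edgeR adjusted p = 0.539).

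Of the 33 round spermatid genes, 31 lay below 0, with 8 lower when adjusted over the list alone and 9 by DESeq2. Catsper1, a subunit of the sperm calcium channel, was at 174 ± 57.2 against 19.7 ± 4.04 CPM (log2 fold change -3.14, SE 0.58, DESeq2 adjusted p = 6.58e-05, edgeR adjusted p = 0.133). The spermatid kinase Tssk2 was at 575 ± 717 against 20.2 ± 9.86 CPM. Hook1, needed for shaping the sperm head, was at 959 ± 325 against 187 ± 44.3 CPM. In edgeR, Catsper1 passed without heterozygous replicate 1 or 2 and Hook1 without heterozygous replicate 1. Tssk2 passed without heterozygous replicate 1 and homozygous replicate 1 or 2. Each of these fits left a group with a lone library, so they add no support.

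The spermatocyte lists did not pass camera with all libraries. Pachytene spermatocyte genes had a median of -0.31 over 25 genes (adjusted p = 0.0542). Among them, Calr3, a testis calreticulin, was at 116 ± 75.5 against 8.29 ± 3.18 CPM and Pgk2, a glycolytic enzyme of late germ cells, at 516 ± 506 against 62.3 ± 37.4 CPM, both past the threshold in DESeq2. In edgeR, Calr3 passed without heterozygous replicate 1 or 2 and Pgk2 without heterozygous replicate 1, in fits where heterozygous testis was a lone library. Meiotic prophase genes had a median of -0.27 over 30 genes (adjusted p = 0.0834) with Sycp2, of the synaptonemal complex, at 1048 ± 472 against 776 ± 500.3 CPM, a direction that turned without heterozygous replicate 1 (from -0.43 to 0.11) or homozygous replicate 1 (0.15). In camera the pachytene list was called lower without heterozygous replicate 1 (adjusted p = 0.00471) or homozygous replicate 2 (1.81e-04), and its direction turned to higher without heterozygous replicate 2 (0.875) or homozygous replicate 1 (0.735). Meiotic prophase genes were called lower without heterozygous replicate 2 (0.0148) or homozygous replicate 2 (0.0451).

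Genes of the piRNA pathway had a median of 0.10 over 28 genes (camera adjusted p = 0.644), and its direction turned without homozygous replicate 2 (adjusted p = 0.778). Ddx4, the germ cell helicase, was at 1327 ± 204 against 1018 ± 634 CPM (edgeR adjusted p = 0.900); its direction turned without homozygous replicate 1, from -0.38 to 0.22.

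Among somatic genes, Clu, a secreted Sertoli cell chaperone, had 238 ± 159 CPM in heterozygotes and 605 ± 318 CPM in homozygotes, and Cyp17a1, a steroidogenic enzyme of Leydig cells, 99.8 ± 30.8 and 263 ± 108 CPM. Neither passed in edgeR (adjusted p = 0.617 and 0.488) or DESeq2. DESeq2 called 1 Sertoli gene higher, Shbg, which encodes the carrier of sex steroids, at 0.172 ± 0.243 against 2.97 ± 0.868 CPM. The members with the strongest change in 2 of the higher lists went the other way. Actg2, a smooth muscle actin in the myoid list, was at 279 ± 145 against 18.1 ± 1.64 CPM, and Aif1, a calcium-binding protein in the macrophage list, at 1247 ± 1023 against 58.5 ± 23.9 CPM, both lower by DESeq2 (adjusted p = 4.64e-07 and 7.73e-07). In edgeR, Actg2 passed without heterozygous replicate 1 or 2, and Aif1 without these and without homozygous replicate 1. Each of these fits left a group with a lone library. In the spermatogonial list Dazl, an RNA-binding protein, was at 245 ± 142 against 153 ± 12.6 CPM, a direction that turned without heterozygous replicate 1 (from -0.67 to 0.07). Shbg passed in edgeR without heterozygous replicate 2, again with a lone library in that group.

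The remaining lists did not pass with all libraries: ribosomal proteins (median 0.27 over 70 genes, adjusted p = 0.0542), histones (0.23 over 24, 0.141), interferon response (0.51 over 17, 0.141) and p53 targets (0.34 over 19, 0.151). Nor did transposon control (0.57 over 19, 0.159), endothelium (0.25 over 10, 0.471) and heat shock (0.14 over 17, 0.697). Blood and epididymis had 1 measured gene each, Alas2 at 4.6 ± 0.371 against 8.65 ± 4.72 CPM and Rnase10 at 5 ± 2.57 against 3.11 ± 0.637 CPM, and the mitochondrial list had 0, so these were not tested.

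In camera, ribosomal proteins were called higher without heterozygous replicate 2 (adjusted p = 0.0148), homozygous replicate 1 (0.00702) or homozygous replicate 2 (0.0341). Histones were called higher without heterozygous replicate 2 (1.56e-04) or homozygous replicate 1 (6.72e-07). Heat shock genes were called higher without homozygous replicate 1 (0.0482), and turned direction without heterozygous replicate 1 (0.775) or homozygous replicate 2 (0.319). Endothelial genes turned direction without heterozygous replicate 2 (0.822) or homozygous replicate 1 (0.841). The epididymis list could be tested without heterozygous replicate 2 or homozygous replicate 1 and was called higher there (0.0293 and 1.70e-07). From 5 lists, without heterozygous replicate 1, to 9, without each of the other libraries, were called, and both spermatid lists and the Sertoli list were among them each time.

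With the estimated correlation the unadjusted p was 0.117 for elongating and 0.273 for round spermatids, 0.0452 for Sertoli, 0.0706 for Leydig, 0.202 for spermatogonial, 0.160 for myoid and 0.303 for macrophage genes. Without heterozygous replicate 1 the adjusted p became 0.0875 for Leydig, 0.0822 for myoid and 0.425 for macrophage genes. Without heterozygous replicate 2 it became 0.152 for spermatogonial and 0.149 for myoid genes. Without homozygous replicate 1, 0.0621 and 0.352 for the same lists; and without homozygous replicate 2, 0.485 for macrophage genes.

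Gene by gene, edgeR called 0 of 14332 genes in the testis, where 1453 had an unadjusted p under 0.05 and the smallest adjusted p was 0.133. DESeq2 called 697 genes, 24 higher and 673 lower in homozygotes. EdgeR without the filter on low counts called 361, 2 higher and 359 lower. Without the members of both spermatid lists, 70 measured genes, the counts were 0 by edgeR and 658 by DESeq2, 24 higher and 634 lower. By DESeq2 the largest falls with a clear mean were in genes that nearly vanished. The gene 1700012A03Rik was at 211 ± 191 against 0.911 ± 0.592 CPM, and 4933402N03Rik at 146 ± 21.4 against 0.629 ± 0.702 CPM. Reads of 1700008P02Rik, Cyp2a12 and Dnajb8 in homozygotes were too few for a ratio, with 0.061, 0.051 and 0.038 CPM against 27, 30.9 and 77 CPM. Among the largest rises by DESeq2 were Gstm2, a glutathione transferase, at 13.9 ± 5.99 against 150 ± 118 CPM (log2 fold change 3.44), and the kallikrein gene Klk1b21 at 2.41 ± 1.27 against 15.9 ± 8.54 CPM. The autophagy protease gene Atg4a was another, at 6.61 ± 1.08 against 40.5 ± 36.7 CPM. DESeq2 called these genes and edgeR did not (edgeR adjusted p = 0.156, 0.233 and 0.299). In edgeR, Gstm2 passed without heterozygous replicate 1 or 2 or homozygous replicate 1. Klk1b21 passed without heterozygous replicate 2 and Atg4a without heterozygous replicate 1. Each of these fits left a group with a lone library. DESeq2 also called the heat shock gene Hspa1l lower, at 236 ± 222 against 7.08 ± 1.19 CPM, and the ribosomal protein gene Rps24 higher, where 1 homozygous library held most of the reads: the replicate 2 ratio was 20.9 and the replicate 1 ratio 1.17. Without homozygous replicate 2 its log2 fold change was -0.021.

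The edgeR count, 0 with all libraries, rose whichever library was left out. Such fits leave a group with a lone library, so the spread within that group also leaves the fit. The rise therefore cannot tell whether a single library accounted for the 0 calls, and its cause was not tested. The authors' deposited table listed 734 genes, of which 595 had an adjusted p under 0.05, 13 higher and 582 lower in homozygotes. Of these, 586 were tested by edgeR here, all 586 with the same sign and 585 with an unadjusted p under 0.05, and 584 were also among the 697 DESeq2 calls.

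**Figure D1:**
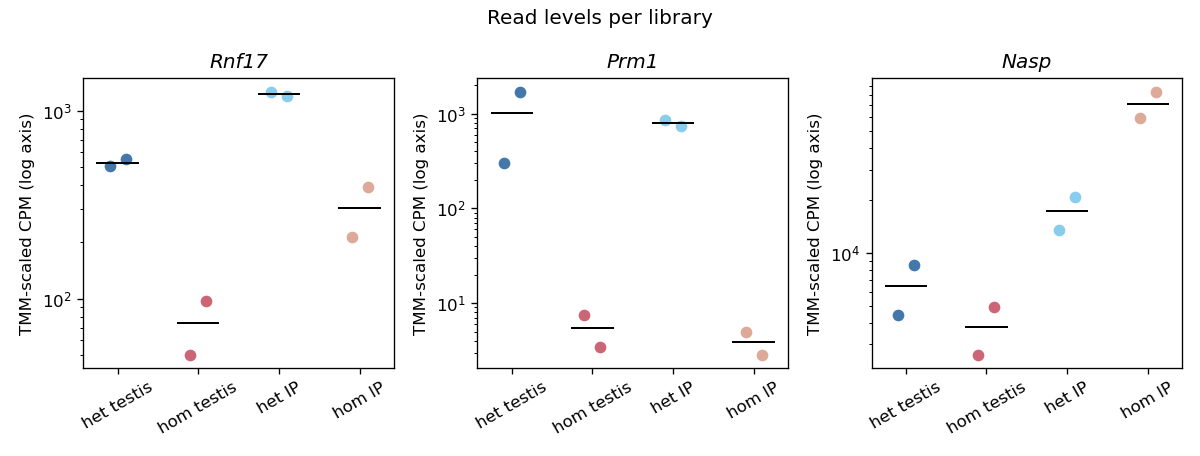
Levels of Rnf17, Prm1 and Nasp in each of the 8 libraries, as CPM on a log axis, with 1 point per library and groups on the horizontal axis. Rnf17 lay at 535 CPM on average in heterozygous and 74.7 CPM in homozygous testis, Prm1 at 812 CPM in heterozygous and 3.73 CPM in homozygous IP, and Nasp at 17588 and 68457 CPM in these IPs.

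Transposon reads were compared because PIWI proteins and their piRNAs hold LINE-1 and IAP elements silent in male germ cells. No transposon entry was called between homozygous and heterozygous testis by edgeR (0 of 1070 entries of uniquely mapped reads, 21 with an unadjusted p under 0.05) or DESeq2 (0). In the simulation this edgeR test recovered 2.9% of 2-fold, 3% of 4-fold and 81.8% of 8-fold changes. The 0 calls thus leave smaller changes open. L1Md families, the young LINE-1 elements, took 7.87 and 1.77 reads per 1000 gene reads in heterozygous replicates 1 and 2 and 4.72 and 4.03 in homozygous replicates 1 and 2. The homozygous to heterozygous ratio was thus 0.6 for replicate 1 and 2.27 for replicate 2. IAP elements, an active family of endogenous retroviruses, took 1 and 0.46 reads per 1000 in heterozygotes and 1.19 and 0.968 in homozygotes, ratios of 1.19 and 2.10. As a class, IAP was the only 1 of 12 that camera called in the testis (higher, adjusted p = 0.0213), with a median log2 fold change of 0.008 over 32 entries where the median of all 1070 entries was -0.283. The IAP call was lost with an estimated correlation (p of 0.261, adjusted p = 0.937 with an estimated correlation).

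Single families spread widely. The L1Md_A antisense entry was at 171 ± 169 CPM in heterozygous and 229 ± 84.3 CPM in homozygous testis, and the sense entry at 274 ± 207 and 166 ± 34.2 CPM. L1Md_F2 was at 1067 ± 1020 and 1126 ± 114 CPM in antisense and at 1629 ± 891 and 742 ± 19.6 CPM in sense. IAPEz-int antisense was at 67.7 ± 69.6 and 120 ± 7.09 CPM. Apart from L1Md_F2 antisense, these were singled out after their values were seen. L1Md_A turned direction without heterozygous replicate 1 in sense (from -0.72 to 0.37), and without heterozygous or homozygous replicate 2 in antisense (from 0.42 to -0.35 and -0.040). L1Md_F2 antisense turned without the same replicate 2 libraries (from 0.078 to -0.67 and -0.056). Of the predefined families, IAPLTR3-int antisense was at 131 ± 38.3 and 129 ± 60.8 CPM, MMERVK10C-int sense at 177 ± 95.1 and 143 ± 19.7 CPM, and B2_Mm2 antisense, a short interspersed element, at 6688 ± 7903 and 3479 ± 4381 CPM. The direction turned without heterozygous replicate 1 for MMERVK10C-int sense (0.37) and B2_Mm2 antisense (1.64), and without heterozygous replicate 2 (0.31) or homozygous replicate 1 (0.47) for IAPLTR3-int antisense.

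With multiply mapped reads, edgeR and DESeq2 also called 0 of 748 entries (3 with an unadjusted p under 0.05), among them IAPEz-int sense at 254 ± 235 and 220 ± 47.3 CPM, which turned direction without heterozygous replicate 1 (from -0.21 to 1.30). Scaling within the transposon table moved the median log2 fold change of all entries by 0.303 for uniquely and by 0.495 for multiply mapped reads, and turned the sign of IAPLTR3-int antisense and MMERVK10C-int sense. The IAP call was also lost with scaling within the transposon table (adjusted p = 0.0909), without heterozygous replicate 1 (adjusted p = 0.906) and without homozygous replicate 2 (adjusted p = 0.957, with the direction turned). Without heterozygous replicate 1, edgeR called 12 entries of uniquely mapped reads, all lower, and 1 of multiply mapped reads.

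The RNF17 IP was compared between genotypes because the homozygous IP measures what the antibody and beads recover without intact RNF17. RNA of elongating spermatid genes was higher in the heterozygous than in the homozygous IP for 33 of 37 measured genes, with a median log2 difference of 3.17, and round spermatid genes were higher for 21 and lower for 4 of 33, with a median of 1.25. Histone genes were higher for 13 of 27 by edgeR and 7 by DESeq2 (median 1.74). Sertoli cell genes were lower for 7 of 27 and higher for none (median -0.62). Camera called these 4 lists, and the calls were lost with a correlation estimated per list (adjusted p = 0.138 for elongating spermatids, 0.404 for round spermatids and 0.649 for histones and Sertoli genes with an estimated correlation). With transposon reads scaled by the gene table, 564 of 977 transposon entries were higher and 17 lower; scaled within the transposon table, 132 of 962 were higher and 170 lower. Reads of 595 olfactory and vomeronasal receptor genes, mostly silent in the testis, stood at 79.3 and 64.7 CPM in the heterozygous IPs and 31.4 and 25.2 CPM in the homozygous IPs. Elongating and round spermatid genes were also lower in homozygous testis, the input of this IP, as given above.

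Prm1 RNA was at 812 ± 71.8 CPM in the heterozygous and 3.73 ± 1.45 CPM in the homozygous IP (SD, n = 2), a log2 difference of 7.78 (SE 0.31, edgeR adjusted p = 1.33e-07), and Prm2 at 1040 ± 29.5 against 5.19 ± 1.66 CPM (7.63). Of the round spermatid genes, Acrv1, an acrosomal protein, was at 193 ± 24.5 against 27.4 ± 3.81 CPM (2.81, adjusted p = 4.44e-06 by edgeR) and Tssk3 at 64 ± 3.71 against 7.54 ± 0.583 CPM. Tssk6 had 40.1 ± 7.19 against 0.274 ± 0.388 CPM, too few reads for a ratio. Hist1h2aa, a testis histone gene, was at 45.6 ± 4.24 against 6.69 ± 2.94 CPM (2.78, edgeR adjusted p = 6.36e-05). Hist1h4j and Hist1h4k passed in edgeR but not in DESeq2 (adjusted p = 0.232 and 0.380), with 0 reads in homozygous replicate 2 each. Of the Sertoli genes, Vim, an intermediate filament, was at 33.2 ± 0.267 against 81.4 ± 6.79 CPM, and Aard and Gstm6 were lower too. The Sertoli call in camera was also lost without homozygous replicate 1 (adjusted p = 0.168).

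Camera called none of the other lists with all libraries, and in several of them members were called both ways. Of 27 piRNA pathway genes, 5 were higher and none lower (camera adjusted p = 0.292, fry adjusted p = 0.0226). Piwil1, the PIWI protein of pachytene spermatocytes, was at 408 ± 24 against 186 ± 33.5 CPM (log2 difference 1.14, edgeR adjusted p = 0.00174), Gtsf1, a PIWI cofactor, at 55.5 ± 19.12 against 10.6 ± 4.16 CPM (2.40), and Gpat2, a factor in piRNA production, at 59.4 ± 11.7 against 26.6 ± 0.639 CPM. Of 30 meiotic prophase genes 5 were higher, among them Rec8, a meiotic cohesin, at 56.5 ± 20 against 11.5 ± 2.60 CPM, and 9 lower, among them Brca2, of DNA repair, at 145 ± 16.1 against 442 ± 64.3 CPM (camera adjusted p = 0.267). Pachytene spermatocyte genes were higher for 5 and lower for 5 of 25 (0.922), with Calr3 at 111 ± 8.94 against 8.13 ± 1.16 CPM, and spermatogonial genes lower for 2 of 17 (0.267). Leydig genes were higher for 1 and lower for 6 of 19 (0.0512), with Scarb1, the lipoprotein receptor, at 56 ± 2.78 against 13.7 ± 0.02 CPM and Hsd3b1, a steroidogenic enzyme, at 18.7 ± 2.12 against 41.5 ± 2.99 CPM. Leydig genes were called lower without heterozygous replicate 2 (adjusted p = 0.0362) or homozygous replicate 2 (0.00188), where camera called 5 lists. Peritubular myoid genes were higher for 1 and lower for 6 of 12 (0.117), macrophage genes higher for 2 and lower for 1 of 16 (0.759) and endothelial genes higher for 1 of 8 (0.817).

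Among stress and housekeeping lists, heat shock genes were higher for 2 and lower for 6 of 16 (camera adjusted p = 0.117), with Hspa1l at 202 ± 64.2 against 9.65 ± 2.54 CPM and Hspe1, a mitochondrial chaperonin, at 22 ± 12.7 against 103.3 ± 33.5 CPM. Ribosomal protein genes were higher for 7 and lower for 10 of 52 (0.267), interferon response genes higher for 2 and lower for 4 of 14 (0.157), p53 targets higher for 1 and lower for 4 of 18 (0.225) and transposon control genes higher for 1 and lower for 3 of 19 (0.355). Of these, Mx1, an interferon-induced GTPase, was not past the threshold without either heterozygous library (adjusted p = 0.258 without replicate 1 and 0.173 without replicate 2) or without homozygous replicate 1 (0.0875). The chromatin regulators Atrx and Ehmt1 were not past it without heterozygous replicate 1 (adjusted p = 0.105 and 0.111), nor Ehmt1 without homozygous replicate 2 (0.0506). Crisp1, an epididymal gene, was at 2.69 ± 0.309 CPM in the heterozygous IP and had 0 reads in the homozygous IP, at least 10.5-fold higher.

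Over all genes, edgeR called 4041 of 13427 in the IP comparison, 2370 higher and 1671 lower in heterozygotes, and DESeq2 called 3519, 2038 higher and 1481 lower. Without the 70 spermatid genes edgeR called 3983. Without heterozygous replicate 1 the count was 2070, 1482 higher and 588 lower. The 5 genes that the naming rule picked as rises had 0 reads in both homozygous libraries, so their order against genes such as Prm1 is not known: 1700080E11Rik was at least 162-fold, 1700011F03Rik at least 115.4-fold, 4933402N03Rik at least 110-fold, the protease gene Prss51 at least 81.2-fold and 1700020A23Rik at least 77.2-fold higher in the heterozygous IP. The largest falls were Rhox3f and Rhox3h, homeobox genes of the reproductive cluster on the X chromosome (log2 difference -3.67 and -3.04), Atg4a (-3.25), Gm4944 (-3.17) and Fam160b2 (-2.98). Nasp, a histone chaperone, was the most abundant gene of all 4 IP libraries, and took 5.51% and 6.85% of the gene reads of the homozygous IPs and 1.57% and 2.27% of the heterozygous IPs. It was at 17588 ± 5439 against 68457 ± 16268 CPM (log2 difference -1.96, SE 0.34, edgeR adjusted p = 0.00123), and was singled out after its values were seen.

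**Figure D2:**
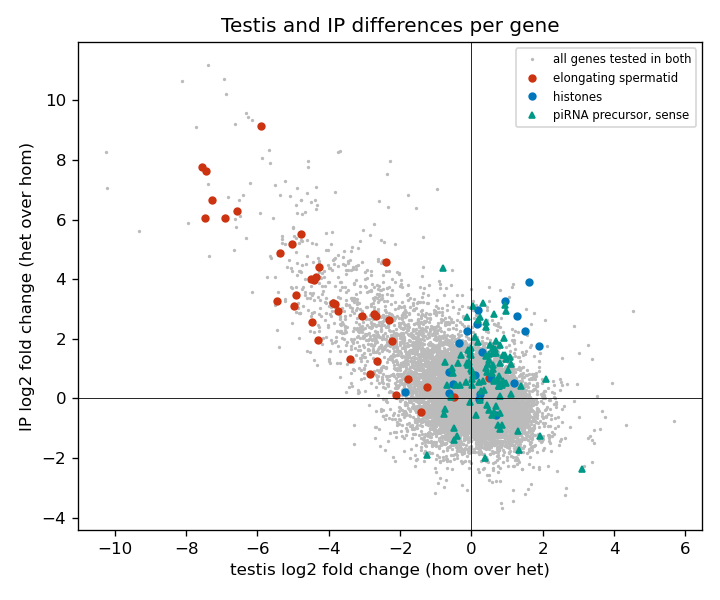
Log2 fold change of each gene in the testis, homozygous over heterozygous, on the horizontal axis, against its log2 difference in the IP, heterozygous over homozygous, on the vertical axis, with 1 point per gene and the elongating spermatid, histone and piRNA precursor sense entries marked. Elongating spermatid genes lie to the upper left, with medians of -4.28 in the testis and 3.17 in the IP.

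Scaled by the gene table, 564 of all 977 transposon entries were higher in the heterozygous IP, so the rise was not particular to endogenous retroviruses or LINE-1. Receptor gene reads were higher there too, and background was not tested for the transposon entries. MERVL-int antisense was at 261 ± 14 CPM in the heterozygous and 17.9 ± 1.25 CPM in the homozygous IP (log2 difference 3.87, SE 0.20, edgeR adjusted p = 2.72e-06), IAPLTR3-int antisense at 269 ± 36 against 46.1 ± 3.66 CPM (2.54), and ORR1A4-int antisense at 88.2 ± 3.25 against 6.68 ± 4.50 CPM (3.74). By class, 11 of 12 L1Md, 18 of 30 IAP, 12 of 14 MERVL, 12 of 18 MERVK10C, 7 of 8 ETn, 93 of 175 other RLTR, 111 of 161 MaLR and 110 of 188 other LINE-1 entries were higher. For short interspersed and older elements the counts were 13 of 28 B1, 6 of 10 B2, 6 of 16 B4 and ID, and 15 of 22 MIR and L2 entries. The IAP, other LINE-1, other RLTR and B2 shares lay near that of all entries. L1Md, MERVL, MERVK10C, ETn, MaLR, and MIR and L2 lay above it, and B1 and B4 and ID below. Lower entries numbered 6 in other LINE-1, 3 in other RLTR and 1 each in IAP, MaLR and B1. HAL1-3A_ME sense, an old LINE-1 relative, was at 2313 ± 445 against 7479 ± 3234 CPM (-1.69, edgeR adjusted p = 0.00625), and B1_Mus1 sense at 940 ± 112.3 against 1969 ± 991 CPM (-1.07, adjusted p = 0.0277), the latter not past the threshold without homozygous replicate 2 (adjusted p = 0.242).

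Heterozygous IP replicate 1 stood apart for some LINE-1 and MaLR families. L1Md_F2 sense was at 9073 ± 10107 against 696 ± 20 CPM, with a heterozygous to homozygous ratio of 22.9 in replicate 1 and 2.83 in replicate 2, and MTB_Mm-int sense at 6770 ± 9514 against 21.5 ± 1.74 CPM, with ratios of 666 and 1.85. Without heterozygous replicate 1 the log2 difference of L1Md_F2 sense was 1.47 instead of 3.71, and that of MTB_Mm-int sense 0.97 instead of 8.30. L1Md families together took 21.8 and 6.05 reads per 1000 gene reads in the heterozygous IPs and 2.09 and 2.03 in the homozygous IPs, and IAP elements 1.11 and 1.24 against 0.388 and 0.407. DESeq2 called 496 of the 977 entries, 480 higher and 16 lower. Scaling within the transposon table, which moved the median by -0.921, gave 302 calls, 132 higher and 170 lower, against 564 and 17. Under it, ETnERV2-int sense, MMERVK10C-int sense and the sense entries of L1Md_A, L1Md_T and IAPEz-int no longer passed (log2 differences between 0.161 and 0.407). For multiply mapped reads edgeR called 0 of 410 entries, where 136 had an unadjusted p under 0.05 and DESeq2 called 193, all higher. The edgeR count was 70 without heterozygous replicate 1, 805 without heterozygous replicate 2 and 2 without either homozygous library.

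**Figure D3:**
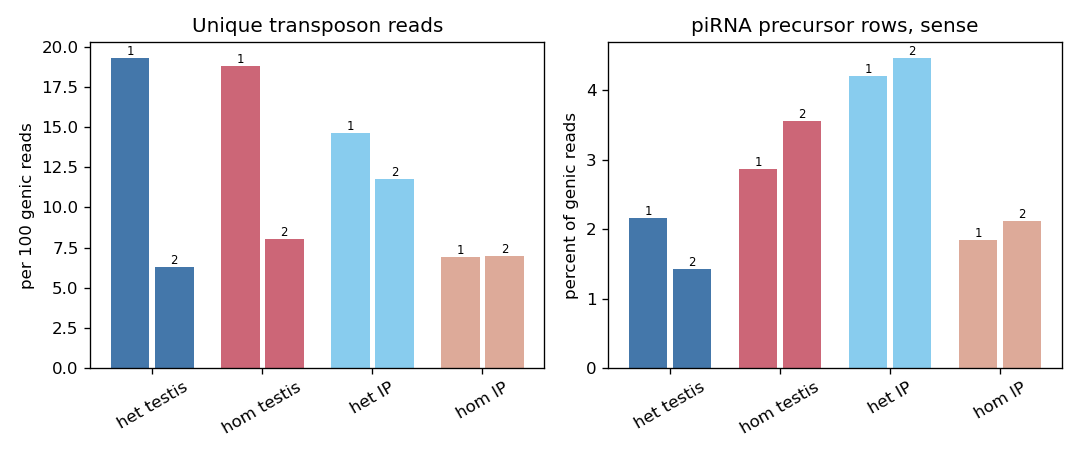
Uniquely mapped transposon reads per 100 gene reads and the percent of gene reads on piRNA precursor sense entries, as 1 bar per library from 0. The replicate 1 testis libraries reach 19.3 and 18.8 transposon reads per 100 gene reads, and the heterozygous IPs hold 4.21% and 4.47% of gene reads on piRNA precursors against 1.85% and 2.12% in the homozygous IPs.

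Each IP was also set against the testis libraries of its genotype, to ask which RNAs the IP enriched. In heterozygotes the histone list was higher in the IP than in the input, with a median log2 ratio of 1.96 over 30 genes, of which 10 were higher when adjusted over the list alone (camera adjusted p = 1.6e-06, and a p of 0.201 with an estimated correlation). Rnf17 RNA itself was at 1207 ± 75.1 CPM in the heterozygous IP and 512 ± 9.98 CPM in the input (log2 ratio 1.24, SE 0.30, edgeR adjusted p = 0.214). It passed without heterozygous testis replicate 1 or 2, in fits where heterozygous testis was a lone library. In homozygotes it was at 309 ± 130 against 75.6 ± 33.5 CPM (2.03, SE 0.47, adjusted p = 0.0396), and the call did not hold without homozygous IP replicate 1 (adjusted p = 0.0555) or 2 (0.484). The log2 ratios of the genotypes differed by -0.82 (SE 0.63, edgeR adjusted p = 0.725). In homozygotes the round spermatid list was called higher (median 0.41 over 32 genes, adjusted p = 0.0395, and a p of 0.469 with an estimated correlation).

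Gene by gene, edgeR called 0 of 13562 genes in the heterozygous IP against input, where 2460 had an unadjusted p under 0.05 and DESeq2 called 597, 306 higher and 291 lower. Of these, Gm5415 was at 489 ± 153 against 9.9 ± 0.943 CPM, Gm9839 at 241 ± 114 against 8.66 ± 3.91 CPM, and Hmgb3, of the high-mobility group chromatin proteins, at 74.5 ± 16.2 against 3.54 ± 3.32 CPM. Lower by DESeq2, 1700019M22Rik was at 39.8 ± 8.98 against 471 ± 449 CPM. The edgeR count was 17 and 11 without heterozygous IP replicate 1 and 2, and 5887 and 7278 without heterozygous testis replicate 1 and 2. In homozygotes edgeR called 438 of 13334 genes, 245 higher and 193 lower, and DESeq2 1317, 700 higher and 617 lower. The largest rises were 4930578N16Rik (11998 ± 3735 against 181 ± 24.7 CPM, log2 ratio 6.05), Gm5415 (5.76), Arf5, a small GTPase of the ARF family (5.63), 4930444G20Rik (5.22) and Gm9839 (5.20). Among the largest falls were Rabggtb, a prenyltransferase subunit (-5.70), and Mageb18 (-4.30). Rabggtb did not pass without homozygous testis replicate 1 (log2 ratio -0.56), the library that held most of its reads. Nasp was at 72872 ± 18145 against 3838 ± 1612 CPM in homozygotes (4.25, edgeR adjusted p = 0.0498) and at 16974 ± 4881 against 6175 ± 2319 CPM in heterozygotes (1.46, adjusted p = 0.225). The homozygous call did not hold without IP replicate 1 or 2. The heterozygous ratio passed without testis replicate 1 or 2. Each of these fits left a group with a lone library. The homozygous count was 192 and 89 without IP replicate 1 and 2, and 2422 and 4556 without testis replicate 1 and 2.

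The interaction sets the IP to input ratio in heterozygotes against that in homozygotes, so that each IP is measured relative to its own testis RNA. Entries for piRNA precursors, the long RNAs from which piRNAs are made, had a higher ratio in heterozygotes: the median log2 difference was 1.16 over the 100 sense entries, 83 of them above 0, and 1.92 over the 64 measured antisense entries, 62 of them above 0. Histone genes had a median of 2.23 over 32 genes, 29 above 0 (camera adjusted p = 2.74e-07), and meiotic prophase genes a median of -0.52 over 30 genes, 22 below 0 (adjusted p = 0.0418). These calls were lost with an estimated correlation (p of 0.114 and 0.197, adjusted p = 0.791 with an estimated correlation for both), where the sense and antisense piRNA precursors had a p of 0.123 and 0.0223. The meiotic prophase median also lay within the range of the random gene lists given below, which were matched to the piRNA precursor sense entries. Spermatid genes did not pass, with a median of -0.59 for elongating spermatids (adjusted p = 0.163) and -0.57 for round spermatids (adjusted p = 0.0865). Prm1 had an interaction of 0.13 (SE 1.05, edgeR adjusted p = 0.983) and Tnp1 of -0.66 (SE 1.12, adjusted p = 0.888). The sign turned for Prm1 without heterozygous testis replicate 1 (-0.66), homozygous IP replicate 2 (-0.23) or homozygous testis replicate 1 (-0.36), and for Tnp1 without heterozygous testis replicate 2 (1.26). Prm1 and Tnp1 were chosen here after their values were seen.

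The piRNA precursor sense entries together took 4.21% and 4.47% of gene reads in the heterozygous IPs, 1.85% and 2.12% in the homozygous IPs, 2.16% and 1.42% in heterozygous testis and 2.86% and 3.56% in homozygous testis. In the direct IP comparison 54 of the 100 sense entries were higher and 12 lower in heterozygotes (median 0.86), and 38 of 55 antisense entries were higher and none lower (median 1.98). Reads of the olfactory and vomeronasal receptor genes given above were higher in the heterozygous IPs too, as shares of all gene reads. In the testis edgeR called none of the 166 measured sense and antisense entries, with medians of 0.43 and 0.43. Heterozygous IP over input had a median log2 ratio of 0.85 for sense and 0.84 for antisense entries, with 18 sense entries higher by DESeq2, and homozygous IP over input of -0.39 and -1.34. For the interaction, 32 sense entries were higher and 2 lower when adjusted over the list alone, and 24 and 1 by DESeq2 over all genes. The entry piRNA_10-qB5.1-221.1_sense was at 605 ± 24.6 CPM in heterozygous IP and 80 ± 1.98 CPM in heterozygous testis. In homozygotes it was at 30.8 ± 0.235 CPM in IP and 46.3 ± 1.5 CPM in testis. Its interaction was 3.51 (SE 0.44, DESeq2 adjusted p = 9.70e-09, edgeR adjusted p = 0.214). The median of the sense entries was 0.77 without homozygous testis replicate 2, and that of the histones 0.85.

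Over all genes, edgeR called 0 of 14180 for the interaction, where 1373 had an unadjusted p under 0.05 and DESeq2 called 228, 30 higher and 198 lower. Of the 5 largest rises by DESeq2, all 5 were piRNA precursor sense entries. The largest falls by DESeq2 were C130060K24Rik (-4.90), Zfp942 (-4.32), Gm4944 (-4.26), 4930578N16Rik (-4.25) and Gm732 (-4.24). EdgeR called these falls without heterozygous testis replicate 1, and Gm4944 and Zfp942 also without replicate 2. In these fits heterozygous testis was a lone library. EdgeR called 259 genes without heterozygous testis replicate 1 and 3 without heterozygous testis replicate 2. Of 1059 transposon entries, edgeR called 1, MERVL-int antisense, which was at 257 ± 14.5 CPM in heterozygous IP, 68.2 ± 43.7 in heterozygous testis, 18.6 ± 1.48 in homozygous IP and 109 ± 32.1 in homozygous testis (interaction 4.46, SE 0.82, adjusted p = 0.0487). Another tool, DESeq2, called 20, and 100 entries had an unadjusted p under 0.05 in edgeR. The MERVL-int call did not hold without heterozygous IP replicate 1 (adjusted p = 0.243) or 2 (0.0755), homozygous IP replicate 1 (0.221) or 2 (0.433), or homozygous testis replicate 2 (0.148). The count was 333 without heterozygous testis replicate 1 and 42 without heterozygous testis replicate 2. For multiply mapped reads edgeR called 0 of 754 entries, where 29 had an unadjusted p under 0.05 and DESeq2 called 7; without heterozygous IP replicate 2 edgeR called 15.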

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

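The piRNA precursor lists were formed after the data were examined, and the tests of the largest entries, of the elongating spermatid median and of the library totals given below were chosen only after the result was seen. With 2 libraries per group, the rule for a library far from its group could not be applied. The results of the next paragraph were flagged because the IP to input ratio differed between heterozygotes and homozygotes in the test of that difference. The spermatid transcripts in the IP and the transposon share of the testis libraries met no such rule and are weighed as patterns.

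The sense entries of piRNA precursors had a median interaction of 1.162 log2 and the antisense entries of 1.919. The histone list had a median of 2.231, between 0.846 without homozygous testis replicate 2 and 4.834 without heterozygous testis replicate 2, with p = 0.114 with an estimated correlation. The meiotic prophase list had a median of -0.524, between -0.799 and -0.212 without 1 library, with p = 0.197 with an estimated correlation. This median lay within the central range, -0.771 to -0.364, of random gene lists matched on the mean expression of the piRNA precursor sense entries. Those lists had the size and expression of another set, so they cannot tell whether the meiotic prophase list stood apart. Lists matched to the meiotic prophase, histone or antisense entries were not drawn, so a trend with abundance was not tested for these. MERVL-int antisense had an interaction of 4.465, between 3.925 and 5.323 without 1 library, and its call did not hold without 5 of the 8 libraries.

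For the piRNA precursor sense entries, the design gives the biological contrast, recovery with intact RNF17 against recovery without it. A trend with abundance was excluded: the highest median among 1000 random gene lists matched on mean expression was -0.151, and their central 95% ran from -0.771 to -0.364. A single library was excluded as well, with a median between 0.772 without homozygous testis replicate 2 and 1.606 without homozygous testis replicate 1. A few genes, Nasp among them, took many reads of the homozygous IPs. There the 20 largest entries held 14.08% and 17.28% of gene reads, against 5.2% and 6.69% in the heterozygous IPs. Leaving them out under TMM scaling gave 1.162 again, a test that cannot tell because TMM already trims such entries. Under library totals it shifted the median by 0.161, from 1.948 to 1.787, so these 20 entries accounted for only that part. The median was lower under TMM, at 1.162, than by totals, so other differences in library composition were not excluded. With an estimated correlation p = 0.123 for the sense entries, so the set as a whole did not stand apart from correlated noise by that test. Reads from genomic DNA or other background in the IPs were not tested as an explanation and stay open. The receptor genes given above stood at 79.3 and 64.7 CPM in heterozygous IPs and 31.4 and 25.2 CPM in homozygous IPs. In testis they stood at 182 and 67.1 CPM in heterozygotes and 92.4 and 55.3 CPM in homozygotes. Their IP to testis ratio was thus higher in heterozygotes for each replicate number, as for the piRNA precursors.

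For the higher spermatid transcripts in the heterozygous IP, the technical explanation weighed was a difference in transcript level of the input. Its predictions were met: the elongating spermatid list had a median interaction of -0.587, with quartiles of -1.484 and 0.027, and the log2 fold changes of testis and IP had r = -0.712 across 3978 genes called in the IP (rank correlation -0.629), 71.8% of them with opposite signs. These genes were also lower in homozygous testis, so the direct IP comparison could reflect what was in the lysate as well as what RNF17 holds. Against its own input, the heterozygous IP was not called higher for the elongating spermatid list. The median log2 ratio was -0.704, with 28 of 37 genes below 0 (camera adjusted p = 0.138). That median was 0.816 between replicate 1 libraries and -1.462 between replicate 2 libraries. The median interaction of the list was 0.634 between replicate 1 libraries and -1.623 between replicate 2 libraries.

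For the higher transposon share in the replicate 1 testis libraries of both genotypes, the design gives no biological contrast, and no biological explanation was tested. Reads from genomic DNA were weighed through 595 olfactory and vomeronasal receptor genes, which are mostly silent in the testis; their summed share was 2.714 times higher in replicate 1 than in replicate 2 of heterozygotes and 1.671 times higher in homozygotes, which met the prediction for genomic DNA. The 3 largest entries did not hold most of the excess, with 20.16% in heterozygotes and 24.77% in homozygotes. They were L1_Mus1, B2_Mm2 and B3, all antisense, in both genotypes, and the limit for this test was set after the result was seen. Another difference in library preparation could give the same receptor values.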

How the results depend on the processing

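Calls without the spermatid lists and library-total scaling were chosen only after the result was seen. Of the values of named genes and families, DESeq2 kept 156 on their side, moved 63 past the threshold and took 4 below it, and DESeq2 size factors kept all 145. Without the filter 196 stayed and 27 came past the threshold. Of the values without 1 library, 766 stayed, 152 came past the threshold, 39 fell below it and 64 turned direction. A fit without 1 library assumes that the lone library of its group varies like the other groups. An estimated correlation took 11 list values below the threshold, and the fry test took 9. In the simulation, 13.6% of genes changed 8-fold were recovered in the testis, 1.5% for the interaction and 98.5% between the IPs.

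Against 0 genes called by edgeR in the testis, DESeq2 called 697 and the fit without the filter 361. For the heterozygous IP over input these were 597 and 1 against 0, and for the homozygous IP over input 1317 and 1469 against 438. For the interaction DESeq2 called 228 genes against 0. For transposon entries by uniquely mapped reads, TMM within the table gave 302 calls between the IPs against 581, and for the interaction DESeq2 gave 20 and no filter 3 against 1. By multiply mapped reads DESeq2 gave 193 and no filter 54 between the IPs against 0, and 7 and 1 for the interaction against 0. Camera with an estimated correlation called 0 lists in the testis against 7 and 0 between the IPs against 4, and fry called 0 in the testis and 3 between the IPs. Those 3 were both spermatid lists and the piRNA pathway (fry adjusted p = 0.0226), while histones (0.182) and Sertoli genes (0.227) did not pass. Of the testis transposon classes, an estimated correlation and TMM within the table called 0 and multiply mapped reads 6, against 1. The cause was not tested.

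The samples of different groups share only a replicate number. With that number as a block, edgeR called 943 genes in the testis, 194 in the heterozygous IP over input, 1010 in the homozygous IP over input, 11 transposon entries in the testis, 21 for the interaction and 16 by multiply mapped reads between the IPs, and IAPEz-int sense by multiply mapped reads in the testis turned to 0.176 with the block. Camera with the block called 10 testis lists against 7, adding pachytene spermatocytes (adjusted p = 0.0459), ribosomal proteins (0.0459) and histones (0.0476), and 4 between the IPs. For the interaction it also called round spermatids (0.0479), and for the heterozygous IP over input elongating spermatids (0.00510, against 0.138). Without the block the medians of these spermatid lists lay below 0, at -0.565 and -0.704. The deviations of replicates from their group had r = 0.588 across 14180 genes between heterozygous and homozygous testis, and between -0.176 and 0.105 for the other pairs of groups.

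Without 1 library, edgeR called from 73 testis genes (without homozygous testis replicate 2) to 1273 (heterozygous testis replicate 1), from 2070 to 5414 genes between the IPs (heterozygous and homozygous IP replicate 1), from 11 to 7278 for the heterozygous IP over input (heterozygous IP and testis replicate 2), from 89 to 4556 for the homozygous IP over input (homozygous IP and testis replicate 2), and from 0 to 259 for the interaction (heterozygous IP and testis replicate 1). Transposon entries ranged from 0 to 12 in the testis and from 0 to 333 for the interaction, and by multiply mapped reads from 0 to 1, from 2 to 805 between the IPs, and from 0 to 15 for the interaction. Called lists ranged from 5 to 9 in the testis and from 3 to 5 between the IPs. Between the IPs, the directions of pachytene, macrophage and endothelial genes, none of them called, turned without 1 library. Called testis classes ranged from 0 without homozygous testis replicate 2 to 6 without heterozygous testis replicate 2, and the adjusted p of IAP in camera from 8.93e-07 without homozygous testis replicate 1 to 0.957 without homozygous testis replicate 2. The cause was not tested.

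Scaled by TMM within the transposon table, these log2 fold changes turned direction. In the IPs, multiply mapped reads, they became -0.946 for L2a antisense, -0.548 for ETnERV2-int sense, -0.42 for MMERVK10C-int sense, -0.062 for MERVL-int sense, -0.253 for MTA_Mm-int sense and -1.403 for B1_Mus1 sense. In the IPs, uniquely mapped reads, they became -0.673 for B3 antisense and -0.863 for ID_B1 sense. In the testis, multiply mapped reads, they became 0.491 for L1Md_F2 antisense, 0.898 for ETnERV2-int sense, 1.108 for IAPEz-int sense, 0.566 for MMERVK10C-int sense and 0.03 for ORR1E sense. In the testis, uniquely mapped reads, they became 0.01 for L2 antisense, 0.106 for IAPLTR3-int antisense, 0.022 for MMERVK10C-int sense and 0.142 for PB1D10 sense. The cause was not tested, beyond the shift of the median given for this scaling.

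These log2 fold changes turned direction without 1 library, and their lowest and highest values without 1 library follow. In the IPs, multiply mapped reads, values without heterozygous IP replicate 1 and without heterozygous IP replicate 2 were Lx9 antisense -0.198 and 6.696 and B1_Mus1 sense -0.386 and 1.904. In the IPs, uniquely mapped reads, values without heterozygous IP replicate 2 and without heterozygous IP replicate 1 were RLTR15 sense -0.193 and 0.032 and ID_B1 sense -0.067 and 0.181. In the testis genes, values without heterozygous testis replicate 2 and without heterozygous testis replicate 1 were Dazl -1.172 and 0.07. In the testis genes, values without homozygous testis replicate 2 and without homozygous testis replicate 1 were Ddx4 -1.196 and 0.216, Hsp90b1 -0.23 and 1.094, Sycp2 -1.317 and 0.153, Rps24 -0.021 and 4.683 and Piwil1 -0.382 and 1.571. In the testis genes, values without heterozygous testis replicate 1 and without heterozygous testis replicate 2 were Hist1h2ba -1.296 and 1.267. In the testis genes, values without homozygous testis replicate 2 and without heterozygous testis replicate 2 were Kdm1a -0.403 and 0.323 and Mdm2 -0.778 and 0.632. In the testis genes, values without homozygous testis replicate 1 and without heterozygous testis replicate 1 were Rpl13a -7.158 and 7.113. In the testis, multiply mapped reads, values without heterozygous testis replicate 2 and without heterozygous testis replicate 1 were L1Md_F2 antisense -0.94 and 0.068, ETnERV2-int sense -0.683 and 0.667, IAPEz-int sense -0.941 and 1.305, MMERVK10C-int sense -1.016 and 0.281 and MERVL-int sense -0.373 and 1.392. In the testis, multiply mapped reads, values without homozygous testis replicate 1 and without heterozygous testis replicate 1 were ORR1E sense -10.051 and 7.966 and B4A sense -3.776 and 0.616. In the testis, multiply mapped reads, values without homozygous testis replicate 1 and without homozygous testis replicate 2 were B1_Mus1 sense -1.619 and 0.014. In the testis, uniquely mapped reads, values without homozygous testis replicate 1 and without heterozygous testis replicate 1 were L1_Mus1 antisense -4.29 and 0.236, L2 antisense -0.858 and 0.348 and B2_Mm2 antisense -4.122 and 1.638. In the testis, uniquely mapped reads, values without homozygous testis replicate 2 and without homozygous testis replicate 1 were IAPLTR3-int antisense -0.573 and 0.474. In the testis, uniquely mapped reads, values without heterozygous testis replicate 2 and without heterozygous testis replicate 1 were MMERVK10C-int sense -0.773 and 0.367, RLTR45-int sense -0.321 and 0.615, ORR1D1 antisense -0.504 and 1.002, L1Md_F2 antisense -0.671 and 1.685, L1Md_A antisense -0.345 and 2.141, L1Md_A sense -1.344 and 0.366, L1Md_T antisense -0.593 and 2.186, L1Md_T sense -1.564 and 0.179 and IAPEz-int sense -0.663 and 1.401. In the testis, uniquely mapped reads, values without homozygous testis replicate 1 and without homozygous testis replicate 2 were PB1D10 sense -0.324 and 0.248 and ID_B1 sense -0.621 and 0.081. In the interaction of genes, values without heterozygous testis replicate 1 and without heterozygous testis replicate 2 were Prm1 -0.664 and 1.836 and Tnp1 -1.474 and 1.261. In the interaction, multiply mapped reads, values without heterozygous IP replicate 1 and without heterozygous IP replicate 2 were L1MC3 antisense -0.806 and 11.562. In the interaction, multiply mapped reads, values without heterozygous IP replicate 1 and without heterozygous testis replicate 1 were L1ME1 antisense -0.928 and 14.341, L1MEc antisense -0.734 and 12.53 and L2b sense -0.519 and 13.212. The families of the last group had 0 reads in the homozygous IPs, so these sizes are not folds. The cause of the other turns was not tested.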

Other observations

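The genes below met the naming rule, and their comparison across testis and IP was chosen only after the result was seen.

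Genes that were lower in homozygous testis and higher in the heterozygous IP included Hspa1l, a testis heat shock gene, with log2 fold changes of -5.06 in the testis and 4.38 in the IP, and Calr3 with -3.81 and 3.77. Aif1 had -4.42 in the testis and 2.23 in the IP, and Actg2 -3.95 and 1.95, which are markers of macrophages and of smooth muscle in the lists used here. Of the endothelial list, Vwf, of blood clotting, was at 18.8 ± 0.312 CPM in the heterozygous and 2.67 ± 0.622 CPM in the homozygous IP (edgeR adjusted p = 1.11e-04). Myh11, a smooth muscle myosin, was at 34 ± 3.26 against 100 ± 25.9 CPM (edgeR adjusted p = 5.15e-04) and Rpl23, of the large ribosomal subunit, at 70 ± 18.4 against 270 ± 125 CPM (7.10e-04).

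Atg4a was higher in the homozygous group in both comparisons, with 40.5 ± 36.7 against 6.61 ± 1.08 CPM in the testis (DESeq2 adjusted p = 0.0239) and 149.9 ± 23.4 against 15.9 ± 4.41 CPM in the IP (edgeR adjusted p = 4.45e-06). Rpl13a took 1.96% of gene reads in heterozygous and 0.918% in homozygous testis replicate 1, and was the largest entry of these libraries, while Odf2 with 0.842% was the largest of heterozygous replicate 2. Across all 13263 genes tested in both, the log2 fold changes of testis and IP had r = -0.605. The rank correlation was weaker, at -0.364, and 60.2% of these genes had opposite signs.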
